A study of Mus musculus with 2 samples.

How the data were processed

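Single-cell RNA and surface protein were measured together in splenic B cells of mice on the BD Rhapsody platform. The cells came from 4 sources, 1 each: the CD23-Cre control (CD23-control), the conditional knockout made with CD23-Cre (CD23-cKO), the mb-1-Cre control (mb-1-control) and the conditional knockout made with mb-1-Cre (mb-1-cKO). Cells of each source were split over 3 conditions of 2 h: resting, 1 µM of the TLR9 ligand CpG-ODN1668 (CpG), and CpG with 5 µM of the p38 inhibitor SB203580. This gave 12 sample tags, 1 per source and condition. The labels say that B cells were enriched by depleting cells that carry NK, T, granulocyte, myeloid or erythroid surface markers. Tags were assigned to source and condition from the words of the deposited metadata sheet. The 2 GEO samples are mixtures and were not used as groups.

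The deposited tables hold counts: molecules per cell for each gene and antibody, after error correction of molecular identifiers and without normalization, per the file headers. The headers name the BD WTA Multiplex Rhapsody Analysis Pipeline, version 1.9, and STAR with the GRCm38 genome is named in the submitters' processing notes. All values were whole numbers, and 0 molecules differed between the tables per tag and the table of all cells. Each table ends after the gene Rrh in alphabetical order. Genes that sort later, such as Tnf, Tlr9, Tnfaip3, Xist and all mitochondrial transcripts, are not analysed here, and 24.2% of the protein-coding genes of the reference sort after that column. Of all protein-coding genes of the reference, 57.4% have a column. Totals and CPM therefore refer to the part of the transcriptome in the tables. CPM are scaled with TMM factors unless they are called plain CPM. Besides 13 antibodies, 12 columns carry dates in place of gene names and were left out, which leaves 16358 gene columns, 15317 of them with a molecule. The antibody IgMa is in the tables but not in the design text. The metadata sheet assigns the CD23-Cre tags to one cartridge and the mb-1-Cre tags to another, while the headers of all 12 tables name a single run, so Cre line and cartridge cannot be told apart, and values of sources from different lines that are set side by side carry that limit.

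The pipeline called 16803 cells, of which 14778 carried 1 tag and were used. Left out were 1914 cells with molecules of several tags (11.4%, median 3124 RNA molecules, against 1981 in cells with 1 tag) and 111 cells without a tag call (median 677). From the tag shares, 1.25% of the cells used were expected to be multiplets of a single tag. The tags held 719 to 1667 cells and 2243022 to 5188138 RNA molecules. No cell was removed by a quality filter in the main calculation, and 73 cells had fewer than 200 genes.

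Molecules were summed per tag, since cells and tags of a source are splits of the same cells and not replicates. The p-values of the condition and interaction tests measure how the effects scatter across the sources, which differ in genotype, and not the spread of levels between sources. For cKO against control they measure the scatter of the cKO effect between the Cre lines. The effects of CpG against resting, CpG plus SB203580 against CpG and CpG plus SB203580 against resting were tested on the 12 sums with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood tests), with source as a block and the sources as 4 replicates. The same tool tested whether these effects differ between the 2 cKO and the 2 control sources (cKO by condition interactions), and cKO against control on 4 sums, 1 per source, with Cre line as a block. P-values are two-sided and were adjusted by the Benjamini-Hochberg method at 0.05. Within a Cre line there is 1 source per arm, so no test was made. Genes with at least 10 CPM in an arm and 20 molecules in each condition were described as higher or lower when the cKO to control ratio was at least 2-fold in all 3 conditions. Ratios against 0 molecules used a floor of 3 molecules per tag and are bounds. Exact Poisson and binomial 95% intervals cover counting error only. Antibody effects of the conditions were tested by exact sign flips over the 4 sources. Resting cells were clustered with scanpy 1.11.5 (2000 variable genes without immunoglobulin variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5 with igraph 0.11.9), and clusters were named only from fixed markers. Other tools were limma 3.58.1 (camera), DESeq2 1.42.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

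The contrasts, tests, gene lists, markers, alternatives and the rule for naming genes were chosen before the data were examined. For a tested contrast the rule names the 10 largest and 10 smallest log2 fold changes among genes past adjusted p 0.05 with the same sign in every source and a mean of at least 20 CPM. Within a Cre line it names the 10 largest and 10 smallest mean log2 ratios among genes that meet the size rule. Pten and up to 4 members of each list, the 2 with the largest and the 2 with the smallest change, were added. Immunoglobulin variable, Xist and Y-linked genes were counted but not ranked. The pathway lists are NF-kB targets and feedback, cytokines and chemokines, immediate early genes, activation and antigen presentation, p38 pathway and mRNA decay, FOXO targets, glycolysis and nutrient transport, cholesterol and fatty acid synthesis, interferon-stimulated genes, MYC targets and ribosome biogenesis, PI3K and PTEN pathway, B cell receptor signalling, endosomal TLR pathway, heat shock and handling stress, and mitochondrial transcripts. Markers cover pan-B, follicular, marginal zone, B-1, transitional, germinal centre, plasma, age-associated B, T, NK, myeloid (monocyte, macrophage or dendritic), neutrophil, erythroid and cycling cells. Members without a column are missing from the lists. The endosomal TLR list keeps 8 of 16 members, without its TLR genes and Unc93b1. The p38 list keeps 17 of 20, without Zfp36, Zfp36l1 and Zfp36l2, and the FOXO list 14 of 20. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Within a Cre line a list's median was placed among 10000 random lists of the same size matched on expression.

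Alternatives were DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, only cells with at least 200 genes, cells with 2 or more non-B markers left out, equal weight per cell with limma, no source block, immunoglobulin genes left out, and leaving out each source. For the comparisons without a test they were a 1.5-fold rule, resting tags only, CPM of the total, medians or shares of antibody molecules, other cluster resolutions, CpG tags, and cells thinned to 1000 molecules. Leaving out cells with fewer than 100 CD19 antibody molecules (CD19-low cells) was added after the data were seen. The tests were tested on simulated data: of genes changed 2-fold, 82.1% were recovered for CpG against resting, 91.0% for SB203580 against CpG, 26.9% and 40.3% for the interactions of cKO with CpG and with SB203580, and 26.9% for cKO against control over both lines. Of genes changed 4-fold, 65.2% to 98.5% were recovered in these tests. False calls were 12 of 168, 14 of 173 and 9 of 167 for the condition contrasts, 12 of 80 and 9 of 95 for the interactions and 31 of 99 for cKO over both lines, above the 0.05 aimed at. The size rule recovered 98 and 93 of 100 genes changed 4-fold in the CD23-Cre and mb-1-Cre pairs and called 0 unchanged genes. These pairs were simulated with counting error only, without spread between sources. False calls that come from such spread were therefore not measured.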

Results

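Pten, the gene that the series names as mutated, encodes the phosphatase that opposes PI3-kinase, and it was measured first in every tag, in plain CPM (molecules over the total, without TMM factors) here. In CD23-control cells it stood at 415, 251 and 347 CPM in the resting, CpG, and CpG plus SB203580 tags, and in CD23-cKO cells at 300.3, 143 and 173 CPM (mean log2 ratio −0.76). In mb-1-control cells it stood at 420.0, 305 and 392 CPM, and in mb-1-cKO cells at 309, 214 and 285 CPM (mean log2 ratio −0.47). With TMM factors the mean log2 ratios of Pten were −0.77 and −0.69, so the size in the mb-1-Cre pair depends on the scaling. Exact Poisson 95% intervals of the resting tags were 393 to 439, 282 to 319, 394 to 448 and 287 to 332 CPM in CD23-control, CD23-cKO, mb-1-control and mb-1-cKO. Resting Cd79a, the mb-1 gene itself, stood in plain CPM at 4202 and 3956 CPM in CD23-control and CD23-cKO cells and at 1955 and 1352 CPM in mb-1-control and mb-1-cKO cells. These values cover all cells of a tag. CD19-low cells made up 15.3% to 17.8% of mb-1-cKO and 2.97% to 3.27% of mb-1-control cells. How far they move the Pten ratio of that pair is not given here. With 1 source per arm there is no test. The libraries read 3′ ends, so transcripts that lost only an upstream part are still counted, and these values need not follow the loss of the protein.

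After 2 h of CpG, Ccl3 and Ccl4, chemokines that draw T cells and myeloid cells, rose from 35.9 to 1099 CPM (log2 fold change 4.96, SE 0.23) and from 118 to 2379 CPM (4.34, SE 0.30), as means of 4 sources. Bcl2l1 and Bcl2a1d, which encode anti-apoptotic proteins, rose from 13.5 to 347 CPM and from 29.0 to 418 CPM, as did the pro-apoptotic Bcl2l11 to a smaller extent (0.69), and Il2ra, the high-affinity chain of the IL-2 receptor, rose from 53.2 to 972 CPM. Nfkbiz, a nuclear cofactor of NF-kB, rose from 122 to 1893 CPM (log2 fold change 3.97, SE 0.06, edgeR adjusted p 2.6e-13). The interleukins Il1a and Il1b rose from 6.40 to 133 CPM and from 15.7 to 219 CPM, the transcription factor Hnf1b from 5.59 to 269 CPM and the amino acid oxidase Il4i1 from 31.7 to 383 CPM. In the other direction Pik3ip1, an inhibitor of PI3-kinase, fell from 97.4 to 14.4 CPM (log2 fold change −2.79, SE 0.18), and Cpt1a, which brings fatty acids into mitochondria, from 135 to 27.0 CPM. Fcrla, an Fc receptor-like protein of B cells, fell from 307 to 55.2 CPM and the transcription factor Hhex from 37.6 to 6.79 CPM. The others named by the rule were B3gnt7, Plekho1, Rnase6, AI467606, Gm15675 and Lbh, with log2 fold changes from −2.96 to −2.41.

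Of 16 tested NF-kB targets and feedback genes 15 rose and 0 fell, from Nfkbiz (log2 fold change 3.97) and Bcl2a1d (3.83) to Relb (0.43), while Bcl3 did not pass (−0.11). Of 14 activation and antigen presentation genes 12 rose, among them Il2ra (4.30) and Cd83 (1.89), and Ciita, the master regulator of class II genes, fell (−1.36). Myc rose from 202 to 1640.3 CPM, and 14 of 15 MYC targets and ribosome biogenesis genes rose (Polr1b 1.69, Nolc1 1.52). Of 14 cytokines and chemokines 8 rose and 2 fell, the latter Ltb (−1.05), which shapes lymphoid tissue, and the growth factor Csf1 (−1.76). The 18 immediate early genes went both ways, 8 up (Fosl1 2.40) and 5 down (Fos −1.38). Cholesterol and fatty acid synthesis genes rose in 7 of 11 cases, or 8 adjusted over the list alone (Idi1 1.48, Fasn 1.04), and Dhcr24 fell (−0.77). Heat shock and handling stress genes rose in 8 of 10 cases and fell in 1 (Hsp90aa1 0.71, Dnajb1 −0.45), and glycolysis and nutrient transport genes in 6 and 1 of 11 (Pgam1 1.04, Gpi1 −0.29).

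Genes of B cell receptor signalling mostly fell with CpG, 9 of 15 with 2 up, with Fcgr2b, an inhibitory Fc receptor, at −1.71 and the kinase Btk at −1.32. Of 8 pan-B markers 5 fell and 0 rose (Cd22 −1.29, Cd79b −1.06), and of 15 PI3K and PTEN pathway genes 6 fell and 2 rose (Inpp5d −1.44, Rictor 0.46). FOXO targets were divided, 6 up and 5 down of 12, with the homing receptor Ccr7 at 1.77 and the cell cycle inhibitor Cdkn1b at −2.24 (median 0.07, mean −0.42; 4 up and 5 down, median −0.02, with equal weight per cell). The same was true of p38 pathway and mRNA decay genes, 7 up and 4 down of 15, with the phosphatase Dusp16 at 1.12 and Mapk14, which encodes p38α, at −2.16 (median 0.21, mean −0.04; 4 up and 5 down with equal weight per cell). Endosomal TLR pathway genes were divided 3 to 3 of 7 (Irf8 1.22, Irak3 −1.18, median −0.16, with camera upward). Interferon-stimulated genes gave 1 of 7 up (Isg15 1.39) and 1 down, or 0 down adjusted over the list alone (median −0.02, mean 0.02; median 0.04 with DESeq2 size factors). Mitochondrial transcripts have 0 members in the tables.

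Among the marker lists, 3 of 5 follicular markers rose and 2 fell (Cxcr5 1.11, Klf2 −0.77), 2 of 8 marginal zone markers rose and 3 fell (Marcks 0.61, Dtx1 −1.48), and 2 of 7 B-1 markers rose and 1 fell (Anxa2 0.57, Ahnak −0.38). Of 5 plasma cell markers 2 rose, led by Irf4, a regulator of plasma cell fate (2.67, 295 to 1872 CPM), although the median was −0.12 and the mean 0.41 (median 0.07 with equal weight per cell). Transitional markers gave 1 up of 3 (Cd24a 0.54), germinal centre markers 1 up and 1 down of 4 (Fas 1.31, Mybl1 −1.40; 2 and 1 adjusted over the list alone; median −0.15, with camera upward), age-associated markers 1 up of 2 (Fcrl5 0.74) and cycling markers 2 up and 1 down of 9 (Mcm3 0.39, Mcm6 −0.80; median 0.16, or −0.07 with equal weight per cell, with camera downward). Of the markers of other cells, 0 of 5 T cell and 0 of 7 erythroid markers passed, 1 of 3 NK markers fell (Nkg7 −0.76; 0 adjusted over the list alone), 1 of 10 myeloid markers rose and 1 fell (Flt3 1.61, Ccr2 −1.79, median 0.04, mean −0.02), and 1 of 7 neutrophil markers rose (Retnlg 2.68).

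In all, edgeR called 4136 of 7375 genes in CpG against resting, 1913 up and 2223 down. The majority depends on the method: with DESeq2 size factors the split was 2110 up and 2003 down, and with the DESeq2 Wald test 1911 and 1677. With equal weight per cell it was 1241 up and 2921 down, and the median log2 fold change of all genes moved from −0.09 to −0.26. The PI3K and PTEN list went from 2 up and 6 down to 0 and 8 under that weight. With camera at the preset correlation 9 of 27 lists were called. The NF-kB list (adjusted p 5.87e-45; adjusted p = 0.00126 with an estimated correlation) and the activation list (3.34e-08; adjusted p = 0.0148 with an estimated correlation) held. The other calls did not: MYC targets (1.40e-14; adjusted p = 0.313 with an estimated correlation), cytokines (0.00227; 0.313), plasma cell markers (0.00541; 0.313), immediate early genes (0.0237; 0.504), cholesterol synthesis (0.0237; 0.504), follicular markers (0.0237; 0.413) and pan-B markers, downward (0.0366; 0.650).

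**Figure D1:**
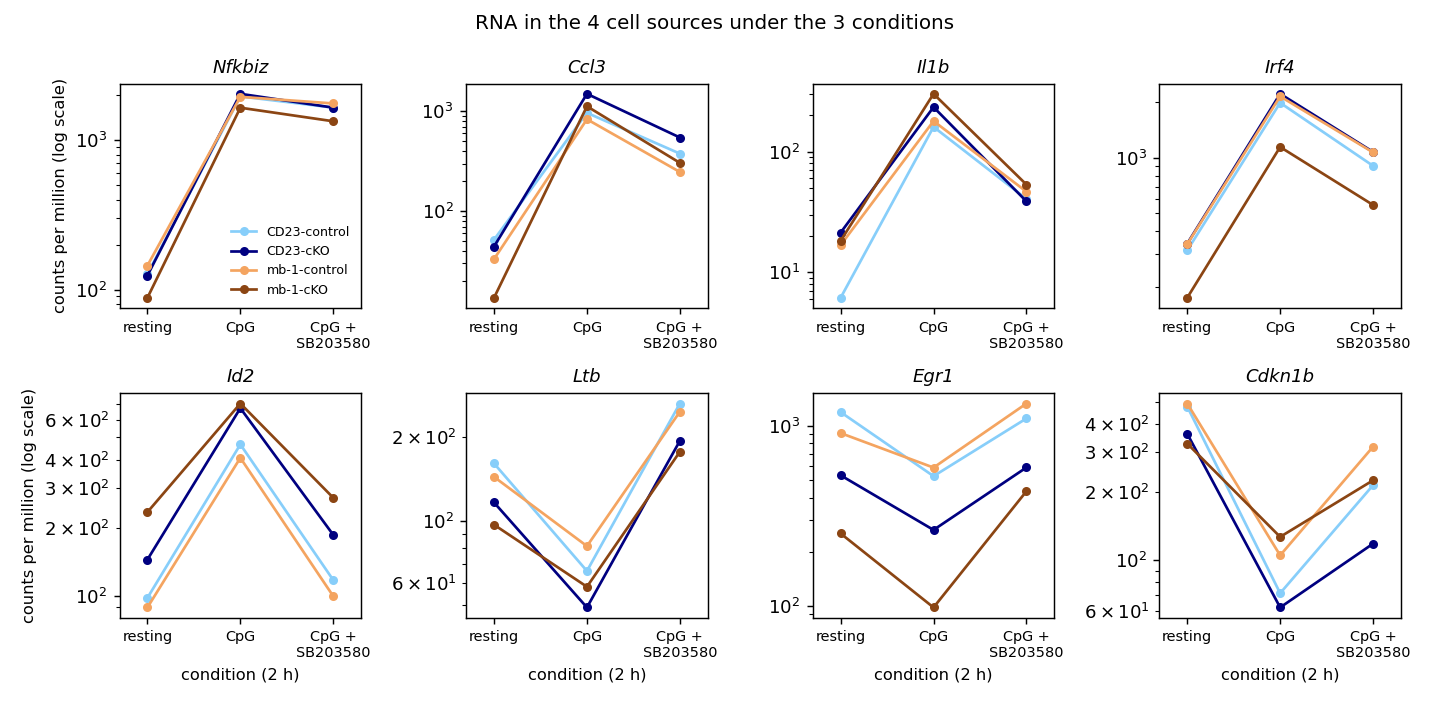
CPM of 8 genes (log scale) in each of the 4 cell sources under the 3 conditions. Lines join tags of the same source.

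**Figure D2:**
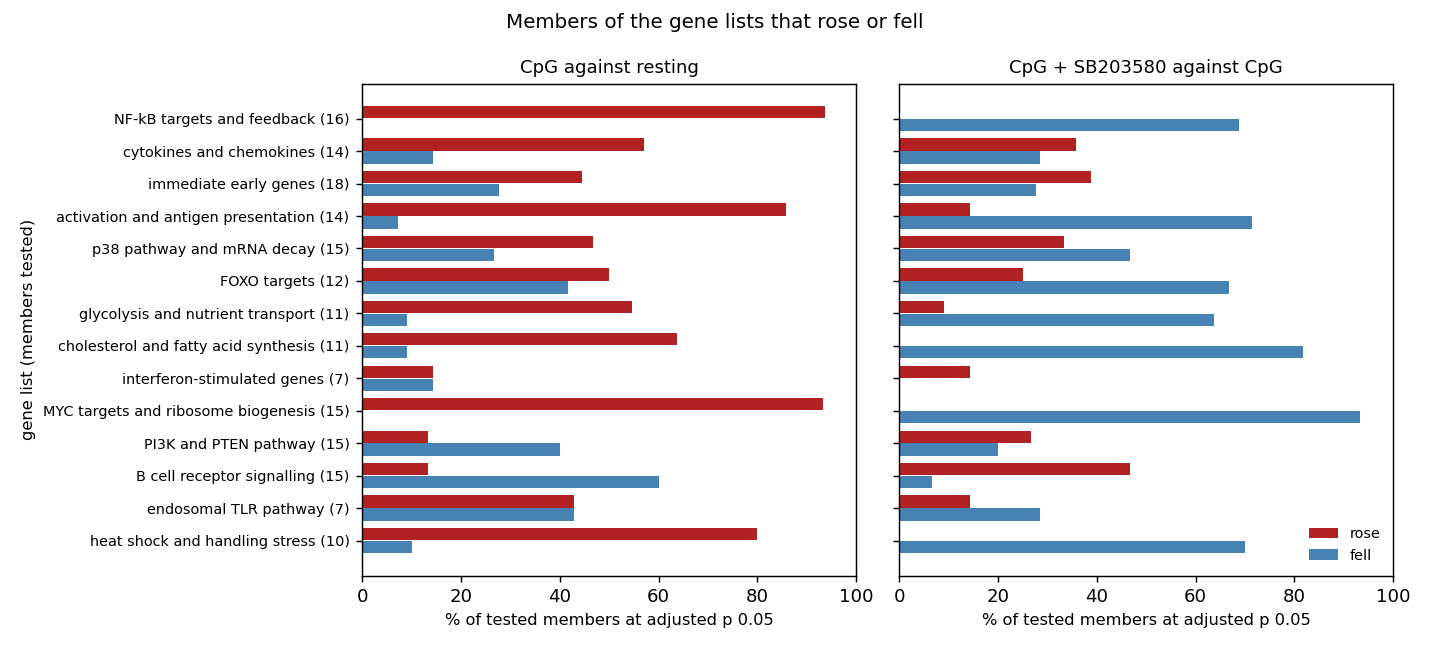
Percent of the tested members of each pathway list that rose or fell (edgeR, adjusted p 0.05) with CpG against resting and with SB203580 added to CpG.

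Adding the p38 inhibitor SB203580 lowered a set of CpG-induced genes and raised genes that CpG had lowered. Il1a fell from 133 to 15.9 CPM (log2 fold change −3.11, SE 0.27) and Il1b from 219 to 45.1 CPM (−2.26, SE 0.15), as means of 4 sources. Id2, an inhibitor of basic helix-loop-helix factors, fell from 562 to 170.3 CPM, and Dusp10, a phosphatase that switches off p38 and JNK, from 133 to 37.2 CPM (log2 fold change −1.85, SE 0.11, edgeR adjusted p 6.0e-07). Kctd14, Gprc5a, Fam129b, Abtb2, Alpl and Mfsd2a also fell, with log2 fold changes of −2.45 to −1.72. Ltb rose from 63.6 to 222 CPM (log2 fold change 1.82, SE 0.10) and Il12a, a subunit of IL-12, from 28.5 to 80.6 CPM (1.53, SE 0.12). Hhex rose from 6.79 to 27.5 CPM, the chemoattractant Il16 from 29.1 to 106 CPM, and the interferon-inducible GTPases Gbp5 and Ifi47 from 17.2 to 60.1 CPM and from 20.2 to 58.4 CPM. Rassf5, Arl5c, Dtx3l and 9930111J21Rik2 were also among the 10 largest rises (1.54 to 1.98).

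Growth and metabolism lists mostly fell when SB203580 was added: 14 of 15 MYC targets and ribosome biogenesis genes (Nop58 −0.91, Ncl −0.91), 9 of 11 cholesterol and fatty acid synthesis genes (Idi1 −1.16, Fasn −0.73), 7 of 11 glycolysis genes with 1 up (Hk2 −0.90, Gpi1 0.22, 8 and 1 adjusted over the list alone) and 7 of 10 heat shock genes (Hsp90aa1 −0.83). Myc fell from 1640.3 to 824 CPM. Of 14 activation and antigen presentation genes 10 fell and 2 rose, with the adhesion receptor Cd44 at −1.28 and Cd69 at 0.55. Of 16 NF-kB genes 11 fell, or 13 adjusted over the list alone (Cflar −0.92, Nfkbid −0.82), and 0 rose. Egr1 rose from 368 to 867 CPM, and immediate early genes were divided 7 up to 5 down of 18 (Egr1 1.37, Fosl1 −1.18; 7 and 6 adjusted over the list alone; median −0.04, mean 0.01, median 0.17 with equal weight per cell). Cytokines were divided 5 to 4 of 14 (Ltb 1.82, Ccl22 −2.28; 5 and 6 adjusted over the list alone; 4 and 5 with DESeq2 size factors; median −0.73, with camera upward), FOXO targets 3 to 8 of 12 (Cdkn1b 1.24, Il7r −1.56), and p38 pathway and mRNA decay genes 5 to 7 of 15 (Mapk14 0.91, Hspb1 −1.15; 7 and 7 adjusted over the list alone; 7 and 5 with equal weight per cell; median 0.18, mean −0.03).

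With SB203580, of 15 B cell receptor signalling genes 7 rose and 1 fell (Cd79b 1.02, Ptpn6 0.96, Malt1 −0.69), and of 8 pan-B markers 4 rose and 0 fell (Cd19 0.58). PI3K and PTEN pathway genes were divided 4 up to 3 down of 15 (Pik3r1 0.64, Mtor −0.60; 4 and 5 adjusted over the list alone), which became 7 to 1 with equal weight per cell and 3 to 5 with DESeq2 size factors. Follicular markers were divided 2 to 2 of 5 (Fcer2a, the CD23 gene, 0.62, Ccr7 −0.74, median 0.03, mean −0.01), marginal zone markers 3 to 3 of 8 (Asb2 1.57, Cd9 −0.71), B-1 markers 1 to 3 of 7 (Itgb1 −0.61, median −0.20, mean 0.03), transitional markers 1 to 1 of 3 (Cd93 0.89, Cd24a −0.47) and endosomal TLR genes 1 to 2 of 7 (Irak3 0.80, Irak2 −0.32, median −0.17, mean 0.03; 2 to 0 with equal weight per cell). Of 7 interferon-stimulated genes 1 rose (Bst2 0.33, median −0.23, with camera upward), of 5 plasma cell markers 2 fell, and 1 myeloid and 1 cycling marker fell. No germinal centre, age-associated, T cell, NK cell, neutrophil or erythroid marker passed.

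For SB203580 against CpG, edgeR called 3088 genes, 1540 up and 1548 down. The split was 2245 to 676 with equal weight per cell, where the median of all genes moved from 0.05 to 0.21, and 1013 to 1537 with the DESeq2 test. Camera called 9 of 27 lists at the preset correlation and 0 with an estimated one. The calls were MYC targets (adjusted p 1.45e-12; adjusted p = 0.321 with an estimated correlation), cholesterol synthesis (4.99e-06; 0.212), NF-kB (4.29e-05; 0.168), activation (1.56e-04; 0.168), heat shock (2.07e-04; 0.321), plasma cell markers (0.00592; 0.212), FOXO targets (0.00913; 0.537) and glycolysis (0.00913; 0.537), all downward, and B cell receptor signalling, upward (0.0463; 0.871).

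Of the 1913 genes that rose with CpG 1246 fell when SB203580 was added (65.1%), and of the 2223 that fell with CpG 1170 rose (52.6%); 44 rose in both steps and 51 fell in both. Median log2 changes with SB203580 were −0.34 for the genes that CpG raised and 0.42 for those it lowered. Both contrasts use the same CpG tags, which alone ties them together. Independent calls would give 401.5 and 464.2 genes in opposite directions and 399.5 and 466.6 in the same. Simulated libraries without any condition effect gave 0.05 in each opposite direction. On average they held only 0.5 genes up and 0.55 down with CpG. Their overlap was thus near 0 by design and does not measure the tie through the shared tags. Across genes, which are not independent replicates, r was −0.69 and the covariance −0.265, against −0.48 and −0.0235 in simulation (difference in covariance −0.241). When each contrast was taken from a different pair of sources, r was −0.54 to −0.48 and the covariance −0.280 to −0.197. The opposite calls then numbered 229 to 860 (3.32 to 4.21 times independence) for genes that rose and 100 to 523 (3.01 to 3.56 times) for genes that fell.

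NF-kB targets stood above the resting level in cells with CpG plus SB203580. Nfkbiz stood at 1606 CPM against 122 (log2 fold change 3.73, SE 0.06), Bcl2l1 at 256 against 13.5 and Icam1, an adhesion molecule, at 417 against 41.7 (3.29, SE 0.13), and 15 of 16 NF-kB genes rose while Bcl3 fell (−0.44). Ccl3 stood at 370 against 35.9 CPM, Il2ra at 512 against 53.2 and Hnf1b at 97.6 against 5.59, and Cdk5r1, Bcl2a1d, Ccl4 and Il4i1 rose by 2.96 to 3.25. B3gnt7, a glycosyltransferase, fell further than with CpG alone, from 91.9 to 4.27 CPM (log2 fold change −4.49), and Plk2, Rnase6, Dtx1, Ddit4, Pik3c2b, Gm15675, Csf2rb, Cpt1a and Gcnt1 fell too (−2.09 to −1.94). Cytokines rose in 9 of 14 cases and fell in 1, immediate early genes in 11 and 1 of 18 (Myc 2.09, Fos −0.64; 11 and 2 adjusted over the list alone), MYC targets in 13 and 0 of 15 (Nop16 0.86) and activation genes in 8 and 6 of 14 (Cd69 1.83, Ciita −1.14). FOXO targets fell in 6 of 12 cases and rose in 1 (Il7r −1.59, Ccr7 1.04). Of the other pathway lists, 7 of 15 PI3K and PTEN genes fell and 1 rose, 6 of 15 B cell receptor signalling genes fell and 2 rose (7 and 2 adjusted over the list alone), and p38 pathway genes were divided 3 up to 5 down of 15 (4 and 6 adjusted over the list alone; 3 and 2 with the DESeq2 test). Cholesterol synthesis genes were divided 2 to 2, glycolysis genes 3 to 2 and heat shock genes 0 to 2, and 4 of 8 pan-B and 2 of 8 marginal zone markers fell with 0 up.

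For CpG plus SB203580 against resting edgeR called 2391 genes, 1177 up and 1214 down, and 1528 without CD23-control or 1608 without CD23-cKO. Camera called 7 of 27 lists. NF-kB (adjusted p 6.48e-63; adjusted p = 0.000663 with an estimated correlation), cytokines (3.55e-08; 0.0402) and activation (2.01e-05; 0.0402) held, while MYC targets (2.17e-05; adjusted p = 0.667 with an estimated correlation), immediate early genes (1.25e-04; 0.271), follicular markers (0.00454; 0.271) and FOXO targets, downward (0.00590; 0.544), did not.

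Whether the responses differ between cKO and control cells was tested next. For CpG the cytokine list had a median interaction of 0.38, with an interaction above 0 for 2 of 14 members when adjusted over the list alone. For SB203580 the cytokine median was −0.33 and that of interferon-stimulated genes −0.60. No gene passed over all genes: edgeR called 0 of 7375 for cKO by CpG (360 at an unadjusted p under 0.05; DESeq2 0, with 115 at that level) and 0 for cKO by SB203580 (274; DESeq2 1, Mt1, a metal-binding protein, at −1.30, named after its value was seen). Without CD23-cKO edgeR called 58 and 10 genes, and without mb-1-cKO 2 and 11, with the lone cKO source then assumed to vary like the others. Over the list alone, the interaction with CpG was above 0 for 2 activation, 1 FOXO, 2 PI3K and PTEN, 2 follicular and 1 transitional gene. That with SB203580 was above 0 for 1 immediate early and 1 endosomal TLR gene and below 0 for 1 plasma cell marker. Camera called 3 lists for CpG, among them immediate early genes, downward (adjusted p 0.0384; adjusted p = 0.660 with an estimated correlation), and 8 for SB203580, of which 0 held (estimated-correlation adjusted p of 0.377 to 0.396). Whether the myeloid and neutrophil lists called here follow the non-B cells of a source was not tested. With SB203580 added, the myeloid marker Lyz2 went from 919 to 1311 plain CPM in mb-1-cKO and from 7.27 to 70.2 in mb-1-control.

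Over both Cre lines, cKO against control is given as values. Egr1, an early response factor, had a log2 ratio of −1.38 (SE 0.22), Pik3ip1 −0.94 (SE 0.14), the B-1 markers Lgals1 and Anxa2 1.95 (SE 0.36) and 1.87 (SE 0.49), Il6 1.78 (SE 0.34) and the LDL receptor Ldlr 0.82 (SE 0.16), with edgeR adjusted p 0.658 for each. Markers of other cells had larger values (Hba-a2 3.46, Ccr2 3.42), and 15.3% to 17.8% of mb-1-cKO cells were CD19-low. No gene was called by edgeR among 8331 (611 at an unadjusted p under 0.05), and DESeq2 called 45. Adjusted over the list alone, 3 cytokines and 4 B-1 markers were higher, 1 erythroid marker was higher and 1 FOXO target was lower. Members of the B-1 list were also raised in resting clusters of other cells, as given below. Camera called 19 of 28 lists at the preset correlation, with follicular markers (adjusted p 1.94e-05), immediate early genes (1.52e-07), NF-kB (4.82e-04) and FOXO targets (0.00165) lower and B-1 markers (2.43e-05) and cholesterol synthesis (2.88e-04) higher. None held (adjusted p = 0.545 with an estimated correlation for each of these). There is 1 residual degree of freedom.

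Within the CD23-Cre pair few genes differed by 2-fold in all conditions, 8 higher and 11 lower in cKO cells of 5847. Il9r, the IL-9 receptor, was lower (3.96 CPM pooled over conditions, Poisson 95% interval 2.93 to 5.24, against 47.7, interval 43.5 to 52.1; mean log2 ratio −3.66), as was Ighg2b (mean log2 ratio −2.22, 4.41 against 22.0 CPM), while Il1a (98.0 against 37.4 CPM) and Kctd14 (129 against 46.2 CPM) were higher. Naip5, a bacterial sensor, was also higher (1.86) and Lmo7, Eps8l1, Mpzl2, Crisp3, Plekhg1, Arhgap31 and Gad1 lower (−1.92 to −1.34), with Gm35082 lower by a bound of −4.35. Rhag, an erythroid gene, was 2.05 in all cells but −0.34 without CD19-low cells. The 19 genes include 1 immunoglobulin variable gene and 3 Y-linked genes.

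By lists, cKO cells of the CD23-Cre pair had more cholesterol and fatty acid synthesis RNA (median log2 ratio 0.60, above all matched random lists; Ldlr 0.94, Idi1 0.84), marginal zone markers (0.40, above all; Myof 0.57), B-1 markers (0.44, percentile 99.98; Lgals1 1.35, Anxa2 1.04), cytokines (0.24, percentile 99.9; Il1b 0.76, Il10 0.75), MYC targets (0.16, percentile 99.99) and plasma cell markers (0.22, percentile 98.1; 94.4, inside the central 95%, without CD19-low cells). They had less of the immediate early genes (−0.29, below all random lists; Egr1 −1.02, Dusp1 −0.67), follicular markers (−0.49, percentile 0.025; Ighd −0.62, Fcer2a −0.52), activation genes (−0.16, percentile 0.07; Ciita −0.62), B cell receptor signalling (−0.17, percentile 0.145), FOXO targets (−0.14, percentile 0.53; Pik3ip1 −0.87), p38 pathway genes (−0.14, percentile 0.685; Dusp4 −0.97) and transitional markers (−0.24, percentile 2.44; 4.50, inside the central 95%, without CD19-low cells). NF-kB (−0.03, percentile 27.9), PI3K and PTEN (−0.04, 17.3), endosomal TLR (−0.05, 19.7), pan-B (−0.11, 5.47), glycolysis (0.09, 87.7), heat shock (0.07, 86.4) and interferon-stimulated genes (0.23, 93.5) lay inside the central 95%. Cycling markers (0.72) and erythroid markers (1.20) were above all random lists and the cycling median was 0.03 without CD19-low cells, and myeloid (−0.60) and neutrophil markers (−3.24) were below all. These percentiles rank lists within 1 pair of sources and are not a test between sources.

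Within the mb-1-Cre pair 395 genes were higher and 62 lower in cKO cells of 6130. The largest ratios belonged to granule and myeloid genes: Mpo, myeloperoxidase, at 479 against 3.39 CPM (mean log2 ratio 7.19), Elane at 271 against 3.04 (6.99), Prtn3 at 353 against 2.98 (6.87), and Gda, Retnlg, Fcnb, Hp and C3 at 5.79 to 7.10, with Ctsg and Nkg7 as bounds of 6.34 and 5.82. Of the cells of mb-1-cKO 15.3% to 17.8% were CD19-low, against 2.97% to 3.27% in mb-1-control, and without CD19-low cells Mpo was 2.08 and Prtn3 0.62 higher and the counts were 80 higher and 50 lower. Among the lower genes were B cell genes: Ighd, the IgD constant region, at 285 CPM pooled over conditions (Poisson 95% interval 273 to 297) against 1503 (1475 to 1531; mean log2 ratio −2.43), Fcmr, the IgM Fc receptor, at 81.6 against 338 CPM (−2.04), and the early response factors Egr1 at 262 against 944 CPM (−2.01) and Egr3 at 30.9 against 155 CPM (−2.28). Without CD19-low cells Ighd, Egr3, Egr1 and Fcmr were at −2.13, −2.05, −1.90 and −1.74. Gm19585, Gm19951, Htra4, Eya1, Gad1 and Hes5 were also lower (−2.83 to −2.10). With plain CPM the split was 511 higher and 30 lower, and the median of all genes moved from −0.09 to 0.14, while of the list medians only those of the p38 (−0.11, then 0.11) and transitional lists (−0.03, then 0.19) changed sign.

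By lists, mb-1-cKO cells had less of the immediate early genes (median log2 ratio −0.60, below all matched random lists, −0.57 without CD19-low cells), NF-kB genes (−0.59, percentile 0.01, then −0.37 and 0.71; Rel −0.81), activation genes (−0.56, percentile 0.01, then −0.33 and 4.73; Il2ra −1.62), follicular markers (−0.93, percentile 0.05, then −0.60 and 0.12; Fcer2a −1.16), FOXO targets (−0.46, percentile 0.66, then −0.34 and 3.69; Pik3ip1 −1.16, Irs2 −1.06), pan-B markers (−0.61, percentile 0.17, then −0.30 and 20.9) and PI3K and PTEN genes (−0.35, percentile 1.46, then −0.22 and 15.02). Of these, the activation, FOXO, pan-B and PI3K lists lay inside the central 95% without CD19-low cells. Source mb-1-cKO had more glycolysis (0.27, percentile 99.9, then 0.18; Pgk1 0.80) and B-1 RNA (0.81, percentile 99.9, then 0.63; Anxa2 2.89, Lgals1 2.56). The B-1 list is not specific to B-1 cells here. Of its 7 members counted in resting clusters, 5 were raised in the B-1-like cluster. In the cluster with T and NK cell markers 4 were raised, and 3 in a cluster with granulocyte and erythroid markers. Whether the B-1 values of either pair follow such cells was not tested. The heat shock list was at 0.10 (percentile 99.7), then 0.000803 (98.7). Cholesterol synthesis (0.18, percentile 94.9; Dhcr24 1.48) and marginal zone markers (0.13, percentile 95.6; Cd1d1 1.29) were inside the central 95% and at percentiles 99.93 and 99.89 without CD19-low cells. Cytokines (0.35, percentile 99.5, then −0.06 and 76.6; Cxcl10 2.91, then 0.25) and plasma cell markers (0.52, percentile 99.4, then −0.33 and 10.8) were inside the central 95% without CD19-low cells. Cycling markers were at 2.33, then at 0.48 and still at percentile 99.99. Myeloid (3.07, then 3.21) and neutrophil markers (5.27, then 3.44) stayed above all matched random lists, and erythroid markers were at 4.26. MYC targets (−0.30, percentile 35.5), B cell receptor signalling (−0.29, 26.8), endosomal TLR (−0.25, 24.3), p38 (−0.11, 58.4), interferon-stimulated (0.33, 76.6, then −0.32) and transitional lists (−0.03, 76.1) lay inside the central 95%.

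Lower in cKO cells of both lines were Arhgap31, a Rho GTPase-activating protein, Gad1, which makes GABA, and Plekhg1 (3 genes, against 0.0908 if the lines were independent), and 0 genes were higher in both. Without CD19-low cells Anxa2, Lgals1 and Lilr4b were higher in both and Ank joined the lower genes. In opposite directions were 1 gene in all cells and 3 without CD19-low cells. Across 5747 genes, which are not independent replicates, r between the lines was 0.28, and 0.40 without CD19-low cells.

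**Figure D3:**
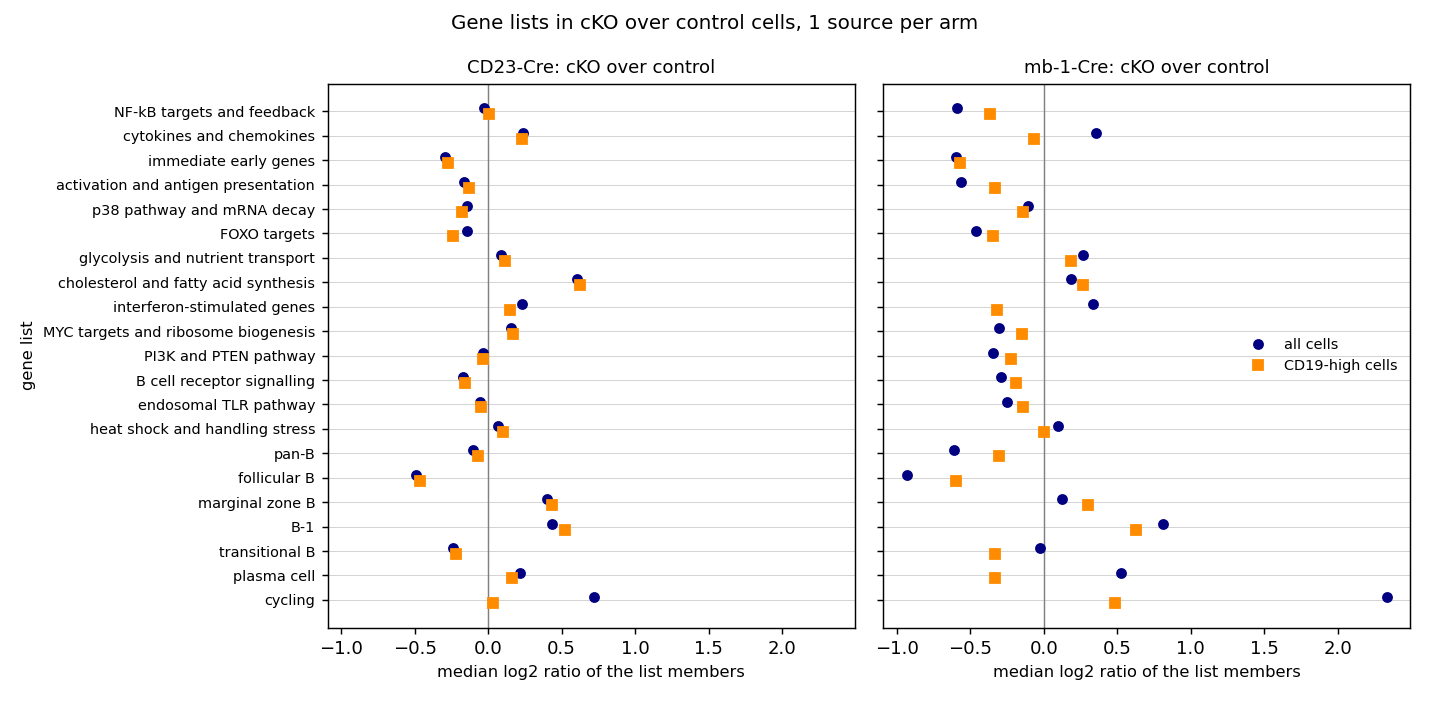
Median log2 ratio of cKO over control for list members in each Cre line, in all cells and without CD19-low cells (CD19-high cells). Myeloid, neutrophil and erythroid markers are left out, and with plain CPM the median of all genes in the mb-1-Cre pair moves from −0.09 to 0.14.

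Surface protein differed between cKO and control cells in the same direction in both lines for several markers. CD23, the low-affinity IgE receptor of follicular B cells, was at 119 against 323 antibody molecules per cell in the CD23-Cre pair and at 104 against 317 in the mb-1-Cre pair (mean log2 ratios −1.44 and −1.60). IgD was at 611 against 1048 (−0.78) and at 52.5 against 1146 (−4.47), the costimulator CD86 at 41.0 against 22.3 (0.88) and at 39.3 against 21.8 (0.85), and class II (I-A/I-E) at 648 against 521 (0.32) and at 791 against 554 (0.52). The complement receptors CD21/CD35 were at 266 against 177 (0.59) and at 280 against 249 (0.16), but by medians the mb-1-Cre ratio was 0.00665, with −0.18 in 1 condition. Mean ratios of CD19, CD45R, CD138 and IgMa lay between −0.29 and 0.22 in both pairs. Median IgMa was 12 to 16 molecules in the tags. It was 11.5 in the resting cluster with T and NK cell markers and 18 in the one with granulocyte and erythroid markers. The IgMa ratios thus lie at antibody background and say nothing of IgM levels. CD40 was at 0.05 (−0.15 to 0.29 by condition) and 0.25 (−0.37 to 0.86), and CD5, CD80 and CD95 were at −0.02, −0.19 and 0.24 in the CD23-Cre pair and at 0.62, 0.90 and 0.70 in the mb-1-Cre pair. By medians the latter were 0.11, 0.25 and 0.49, with CD5 and CD80 below 0 in 1 condition (−0.13 and −0.42). Tag medians were 1 to 4 molecules for CD80 and 5 to 9 for CD95. The resting cluster with T and NK cell markers had medians of 3 and 8, so both ratios rest on counts near antibody background. For CD86 that cluster had a median of 15, against 12 to 14 in the control tags and 23 to 28 in the cKO tags. By medians the CD86 counts of the controls thus lie at antibody background. How far this moves the CD86 ratios was not tested. No test is possible within a pair. After 2 h of CpG class II was higher in 4 of 4 sources (0.20, SD 0.07), CD86 in 4 of 4 (0.08, but −0.0555 by shares of antibody molecules) and CD138, a plasma cell marker, in 0 of 4 (−0.44). Median CD138 was 3 to 5 molecules in the tags and 5 in the resting cluster with T and NK cell markers. Its change thus lies at antibody background, as do the median CD86 counts of the 2 control sources. CD80 was at 0.35 (SD 0.45) and CD40 at 0.20 (SD 0.61). For class II, CD86 and CD138 the exact two-sided p was 0.13, the smallest that 4 sources can give, and adjusted p was 0.696 over 39 tests.

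**Figure D4:**
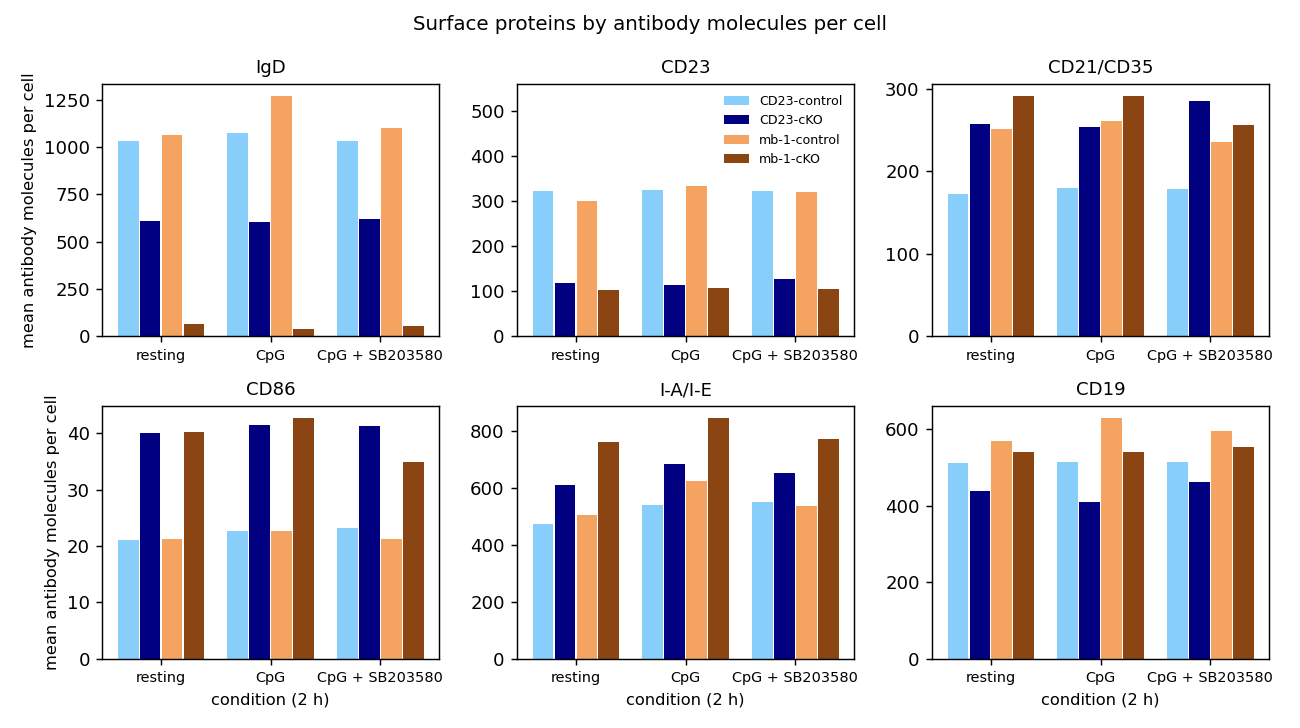
Mean antibody molecules per cell for 6 surface proteins in each source under the 3 conditions.

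Resting cells formed 10 clusters, of which fixed markers named marginal zone B-like, B-1-like and myeloid-like groups, and 6 stayed unnamed. Marginal zone B-like cells, the kind that answers blood-borne antigen, made up 18.8% of CD23-control cells (95% interval 16.8 to 20.9), 28.0% of CD23-cKO (25.6 to 30.4), 29.5% of mb-1-control (26.9 to 32.2) and 42.9% of mb-1-cKO (39.4 to 46.4). They fall in 2 clusters, and CD23-control cells lie mostly in cluster 6 (152 of its cells, against 110 in cluster 3) while mb-1-cKO cells lie mostly in cluster 3 (250 against 96). Il9r and Ighg2b, which differ between the sources, are among the genes that set cluster 3 apart. Plau and the immediate early genes Egr2, Fosl1, Nr4a3 and Myc are among those of cluster 6. With only cells of at least 200 genes, a cluster of 602 cells set apart by these genes stayed unnamed. It held 2 of 8 marginal zone markers. At resolution 1.0 the shares were 11.2%, 11.3%, 11.8% and 11.5%. There a cluster of 329 cells, 236 from mb-1-cKO and 35 from mb-1-control, held too few fixed markers for a name. It had medians of 353 CD21/CD35 and 44 CD23 molecules, and Ighg2b, Ppl and Flt3 set it apart, as they do cluster 3. The shares thus depend on the naming rule, and no direction between sources is given. B-1-like cells were 3.52%, 5.77%, 1.46% and 7.19% of the 4 sources in that order, with Lmo7 among the genes of their cluster. Of 84 myeloid-like cells 85.7% carried CD19 protein.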

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

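The tests of the 3 patterns below, and of other splits of the samples, were chosen only after the result was seen, as was leaving out CD19-low cells. For 123 groups of 4 sources the lowest or highest source was compared with the other 3, and 6 stood far from the rest, where chance gives about 1 in 20, or 6.15. Source mb-1-cKO stood apart in its share of resting CD19-low cells (17.8%, others 3.27% to 5.63%) and in its share of cells with 2 or more non-B markers after CpG (21.3%, others 6.92% to 8.19%). In the same source the 10 most abundant genes held 8.03% of resting molecules (others 8.86% each), and IgD antibody moved by −0.27 log2 between resting and CpG plus SB203580 (others 0.00 to 0.05). Its median IgD was 20 and 17 molecules in these tags, at antibody background (29 in the resting cluster with T and NK cell markers). The −0.27 is therefore not read as a change in IgD. Source mb-1-control stood apart in CD40 antibody after CpG (1.11 log2, others −0.17 to −0.00) and in CD5 antibody when SB203580 was added (−0.40, others 0.12 to 0.16).

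The Cre lines had cKO to control ratios of opposite sign in all conditions for Ighg2b RNA (−2.22 in the CD23-Cre pair and 2.57 in the mb-1-Cre pair, difference −4.79), for CD45R antibody (0.17 and −0.29, difference 0.46) and for CD80 antibody (−0.19 and 0.90, difference −1.09). The antibody signs hold for mean molecules: by shares of antibody molecules both lines were above 0 (CD45R 0.27 and 0.06, CD80 0.12 and 1.85). By medians CD80 was at 0 and 0.25, and without CD19-low cells CD45R in the mb-1-Cre pair was at −0.08 (−0.00712 in the condition nearest 0). Tag medians of CD80 were 1 to 4 molecules, near antibody background (3 in the resting cluster with T and NK cell markers). These differences were not tested, since each arm of a line is a single source. Molecules were also present in data outside the comparisons: in 1914 cells with several tags, in 111 cells without a tag call, and 21838 molecules in the columns that carry dates.

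Myeloid marker RNA was higher in mb-1-cKO cells, at 6657 plain CPM against 251 in mb-1-control, although cells with myeloid surface markers had been depleted according to the labels. Free RNA shared by all cells of a capture was excluded: among cells with CD19 protein the myeloid level was still 8.84 times that of mb-1-control, and 8.37% of these cells held 90.2% of those molecules. Cells of another type in the suspension had what they need, since 87.2% of the myeloid molecules lay in CD19-low cells (70.6%, 30.1% and 51.3% in CD23-control, CD23-cKO and mb-1-control). Some CD19-protein cells with myeloid RNA may be doublets, which was not tested. Whether deletion with mb-1-Cre changes the number of such cells in the spleen stays open and untested, with 1 source.

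IgD was lower in mb-1-cKO cells, with a median of 21 molecules against 918 in resting mb-1-control cells with CD19 protein, a ratio of 0.0229. The resting cluster with T and NK cell markers had a median of 29, so 21 is at the background of the antibody and the ratios of antibody medians here are upper bounds. This bound excludes admixed cells of another type as the whole cause. A weaker stain as the whole cause was excluded by RNA, since the Ighd ratio closest to 0 in the 3 conditions was −2.29 log2. Whether a weaker stain adds to the lower antibody count was not tested. A different mix of the clusters themselves was excluded as the whole cause: within the 3 clusters that hold at least 50 cells of both sources the highest ratio of medians was 0.0482. A different mix of finer classes inside these clusters could give the same ratio and stays open. At resolution 1.0, for example, a cluster with a median of 25 IgD molecules held 236 mb-1-cKO and 35 mb-1-control cells. Lower IgD expression per B cell in this source is thus only a hypothesis. A difference in genotype, which the design names, and any other difference between the 2 sources stay open and untested.

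Y-linked transcripts were lower in CD23-control, at 170 plain CPM against 486, 402 and 356 in CD23-cKO, mb-1-control and mb-1-cKO, which is 41.0% of the mean of those. A difference in scaling left in the values of the CD23-Cre pair was excluded: the median log2 ratio of the genes compared was 0.0300, or 0.0441 in plain CPM. Both scalings place most genes near 0 by design, so these medians say nothing of the libraries before scaling. Cells of male and female mice pooled in this source had what they need: Ddx3y and Eif2s3y met in the same cell more often than by chance, with an odds ratio of 3.07 (95% interval 2.12 to 4.46), above the highest upper bound of the other sources (2.02). The sex of the mice is not named in the labels used here, so a pool of both sexes is a hypothesis, and no biological explanation was tested.

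For the condition contrasts, 35 splits of 8 sums were drawn without regard to the pairing by source, and each was fitted with the source block kept. Of these, 1, the real one, gave as many genes in each contrast: 4136 for CpG against resting (highest other split 0), 3088 for SB203580 against CpG (1) and 2391 for CpG plus SB203580 against resting (0). The sources pair the sums, and 8 of the 35 splits part all 4 sources as the real one does (highest other 0 in each contrast), which are too few for a share under 0.05. The other splits put both sums of at least 1 source on the same side.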

How the results depend on the processing

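Of the tests in this part, those without CD19-low cells were chosen only after the result was seen. Depth limits the genes that can be compared, and the simulated tests above give the fold changes that 4 sources recover. CpG against resting (4136 genes), SB203580 against CpG (3088) and CpG plus SB203580 against resting (2391) kept a count within 1.5 times under every other alternative run except those named here. The 4 sources are a real block, since each was split over the 3 conditions: without the block these counts were 2787, 1351 and 895. Leaving out each source gave 3300 to 4105, 2144 to 2970 and 1528 to 2467 genes, the lowest of the last being without CD23-control (1608 without CD23-cKO). For the interaction of cKO with CpG, 70 genes were called without the filter on low counts and 0 to 58 when a source was left out (58 without CD23-cKO, 2 without mb-1-cKO). For the interaction with SB203580 there was 1 with DESeq2, 65 without the filter and 0 to 11 without a source (10 without CD23-cKO, 11 without mb-1-cKO). For cKO against control over both lines there were 45 with DESeq2, 206 without the filter, 18 without cells with non-B markers and 2 (Ltf and Ngp, named after their values were seen) without CD19-low cells. The cause of these changes was not tested. Not run were the mitochondrial part of the cell filter, since the tables hold no such genes, and leaving out a source for cKO over both lines, where 0 residual degrees of freedom remain.

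Within the CD23-Cre pair 87 genes met a 1.5-fold rule and 125 the 2-fold rule in resting tags alone, a looser rule by construction. Within the mb-1-Cre pair there were 871 and 800, and 130 without CD19-low cells. Rhag reversed to −0.34 there. CD23 antibody was −1.86 by medians and −1.17 by shares in the CD23-Cre pair, and −2.63, −0.74 and, without CD19-low cells, −1.44 in the mb-1-Cre pair. The mb-1-cKO medians of 37 to 38 CD23 molecules lie near antibody background (28.5 in the resting cluster with T and NK cell markers). IgD was −0.94 and −0.64, and −5.67 and −3.33 (both bounds). CD86 in the mb-1-Cre pair was 1.71 by shares, and its CpG effect reversed to −0.0555 by shares. CD21/CD35 in the mb-1-Cre pair was 0.00665, 0.42 and 0.37 by medians, by shares and without CD19-low cells, and class II was 0.39 and 0.41 in the CD23-Cre pair and 0.63, 0.82 and 0.71 in the mb-1-Cre pair. Marginal zone B-like shares at resolution 1.0, at 0.25, with the gene filter and in CpG tags were 11.2%, 13.3%, 4.45% and 10.6% in CD23-control, 11.3%, 18.0%, 13.4% and 20.5% in CD23-cKO, 11.8%, 17.9%, 9.54% and 8.85% in mb-1-control, and 11.5%, 38.5%, 41.0% and 50.5% in mb-1-cKO (50.8% without CD19-low cells). The shares at resolution 1.0 leave out the unnamed cluster of 329 cells described above, and those with the gene filter the one of 602 cells. B-1-like shares in CpG tags were 2.46% in mb-1-control and 5.42% in mb-1-cKO, and Pten in the mb-1-Cre pair was −0.55 in thinned cells. The cause was not tested.

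Named genes kept direction in each condition contrast, and kept their side of the threshold in 1070 comparisons and lost it in 50 for CpG against resting, in 954 and 68 (3 gained it) for SB203580 against CpG, and in 911 and 94 for CpG plus SB203580 against resting. Of the lost calls 23, 31 and 34 came without the source block. Within a Cre line 315 values stayed, 138 moved and 1 reversed. Only genes named by the size rule could count as reversed there. Other list members that changed sign are among the moved values.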

Other observations

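Several small clusters of resting cells carried fixed markers of more than 1 cell type, or of too few to be named, and are given as values. A cluster of 102 cells held markers of granulocytes (8 of 8), erythroid cells (7 of 7) and cycling cells (9 of 9), with a median of 24 CD19 antibody molecules, and 71 of its cells came from mb-1-cKO. A cluster of 224 cells held all 9 cycling markers, 4 of 5 plasma cell and 4 of 7 germinal centre markers, with 38, 58, 27 and 101 cells from CD23-control, CD23-cKO, mb-1-control and mb-1-cKO. A cluster of 50 cells held T cell (7 of 7) and NK cell markers (4 of 4), with 14, 11, 5 and 20 cells. A cluster of 60 cells had a median of 698.5 CD19 and 17.5 IgD antibody molecules, and 54 of its cells came from mb-1-cKO. These markers were counted on the same cells that formed the clusters, so they describe the clusters and are not a test between sources.

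With SB203580 added to CpG, class II protein was at −0.10 log2 (SD 0.10, higher in 1 of 4 sources), CD86 at −0.09 (SD 0.15) and CD80 at −0.35 (SD 0.35), with adjusted p of 0.696, 0.770 and 0.696 from exact two-sided tests over 4 sources. CD19, CD23, CD95 and CD5 means moved by 0.01 to 0.03.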
